A study of Arabidopsis thaliana with 36 samples.

How the data were processed

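The deposited tables hold a raw count of reads per gene for each library, made by the authors against TAIR10 per the submitters' processing notes. The deposited peak lists hold, per peak, its coordinates, strand, a score and the gene, and the authors state neither what the score measures nor which tool, precipitate or input each list came from. The processing notes name STAR 2.7.3a, featureCounts 1.6.2, fastp 0.19.11, BWA 0.7.12, SAMtools 1.7-16, bedtools 2.27.1-1 and Bowtie 1.0.1 without saying which made which table. Per the labels, leaves of 3-week-old plants were treated for 24 h with DC3000 or for 45 min with flg22, and the groups were taken from sample titles and library names, with replicate numbers as given. The labels give no locus for SAIR1, which was taken from the gene name in the deposited peak lists. Gene symbols came from a RefSeq table of the later TAIR10.1 release, used for names only, and coordinates are those of the deposited lists.

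Genes were kept with filterByExpr, scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersions and 1 fit per table. All p for genes are edgeR p adjusted by Benjamini-Hochberg within a comparison, and a call means an adjusted p under 0.05. Translational efficiency was the Ribo-seq change minus the paired RNA-seq change, tested as an interaction in 1 fit over the 16 libraries of both kinds. The labels do not state that both kinds came from the same plants. Deviations of libraries with the same number agreed (r over 0.1) in 1 of 4 groups (-0.023 to 0.2), so groups were compared, not samples. An SE is the log2 fold change divided by the root of F. A fold against a group at 0 is given as a bound with 3 counts over the group as floor, and a gene near 0 in a group is given in CPM. Intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

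Gene lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, and again with an estimated correlation, both adjusted over the lists of a comparison. The 16 lists were the SA pathway; PR and SA-marker proteins; early PTI genes; PTI receptors and kinases; the JA pathway; tryptophan, camalexin and indole glucosinolate genes; nuclear photosynthesis genes; translation factors; guard cell markers; markers of other cell types; ABA response; ER folding; heat shock proteins; clock genes; cytosolic ribosomal proteins; and plastid-encoded genes. Adjusted over the list alone means that only the members of a list entered the adjustment. HSP18.1 was dropped from its list. The list of cytosolic ribosomal proteins held 37 genes taken from the annotation. Results on ribosomal protein genes cover these genes, which may not be the whole family. The list of translation factors also held regulators (TOR, S6K1, GCN2 and RACK1 genes) and the heat shock factor TBF1. Besides SA markers, the list of PR and SA-marker proteins held PR3, PR4 and the defensin gene PDF1.2, so its medians do not read SA alone. The report prints part of the 160 list calls.

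The comparisons, the alternatives, the rule for named genes and 14 of the lists were set before the data were examined. The rule names, per comparison, up to 6 largest rises and falls among called genes with a mean log2 CPM of at least 3 and groups apart, up to 4 members of called lists and of the SA, PR, early PTI and JA lists, genes of the SAIR1 locus, and the RIP-seq genes with the highest scores. Part of these is printed, mostly genes with a symbol and a known role, so the order of the rule was not kept throughout. Chosen after the data were seen were the tables of lists and genes with libraries left out, list medians at the floor, overlap without regard to strand, genes with peaks of both lists on the same strand, translation factors without TBF1, removal of rRNA and organelle genes, and leaving out both DC3000 libraries with the highest rRNA share.

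Peaks were compared on the same strand with at least 1 bp shared, against 100 random placements within genes on the 50 bp grid of the lists. Lists among genes with peaks were compared with 10000 random lists matched on paired RNA-seq level. The shared Col-0 control was weighed with 100 simulations of unchanged groups. Libraries of the same replicate number moved together in the paired RNA-seq (r of 0.17 to 0.29 in 6 of 6 pairs of groups), so counts with a replicate block, 139 for flg22 in Col-0, stand beside its results; they did so in 4 of 15 pairs in the RNA-seq (-0.39 to 0.46) and 1 of 6 in the Ribo-seq (-0.017 to 0.13), where the number is treated as a name.

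Each library was also left out in turn. That leaves a group with 1 library, whose spread the fit takes from the other groups. The code was tested on simulated data with 200 changed genes: 4-fold changes were recovered for 86% of genes in the RNA-seq, 49% in the paired RNA-seq and in the Ribo-seq and 17% for translational efficiency, and 2-fold changes for 41%, 3%, 6% and 1%. Unchanged genes called numbered 13, 6, 5 and 3, beside 127, 52, 55 and 18 changed genes recovered. Sequence motifs, the place of peaks in exons and a peak midpoint in an exon were not run, since they need a genome and exons that were not at hand. Counts of the RIP-seq precipitates and inputs were not analysed here.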

Results

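Leaves of 3-week-old Arabidopsis thaliana plants were profiled in 36 libraries to study SAIR1, an RNA-binding protein of the Bruno-like family, in immunity. In the RNA-seq, 12 libraries covered wild type (Col-0), the mutant sair1-1 and the overexpression line SAIR1-YFP-OX2, 24 h after mock treatment or inoculation with the bacterial pathogen Pseudomonas syringae DC3000. Ribosome profiling (Ribo-seq), which sequences the RNA stretches that ribosomes protect, covered Col-0 and sair1-1 in 8 libraries, 45 min after mock treatment or flg22, a peptide of bacterial flagellin that sets off pattern-triggered immunity (PTI). Another 8 RNA-seq libraries, called paired RNA-seq here, came from those 4 groups. RNA immunoprecipitation sequencing (RIP-seq) comprised 4 precipitated and 4 input libraries of SAIR1-YFP-OX2 and of a line with GFP alone, after 45 min of flg22, and 2 lists of peaks. Every group held 2 libraries (n = 2).

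The total count per library lay between 13.6 M and 21.8 M in the RNA-seq, between 9.45 M and 20.6 M in the paired RNA-seq and between 1.49 M and 4.78 M in the Ribo-seq. Levels are CPM, counts scaled to library size, as mean ± SD, and changes are log2 fold changes ± SE with adjusted p from edgeR. For all 116 gene changes named below as called in a comparison of 1 group with another, both libraries of one group lay above both of the other. The rule for naming the largest rises and falls demands this, so it is no test of those changes.

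SAIR1 (AT4G03110, chromosome 4, 1376306 to 1379747) was read first, since its level checks the genotype of each library. In the RNA-seq it stood at 43.4 ± 0.11 CPM in Col-0 mock and 30.4 ± 1.43 CPM in Col-0 DC3000. The libraries labelled sair1-1 held 301 ± 27.7 CPM under mock and 553 ± 142 CPM under DC3000. The libraries labelled SAIR1-YFP-OX2 held 8.34 ± 2.3 CPM under mock and 3.65 ± 0.193 CPM under DC3000. Against Col-0, the change was 2.79 ± 0.22 under mock (adjusted p = 0.00174) and 4.18 ± 0.23 under DC3000 (adjusted p = 5.62e-05) for the label sair1-1, and -2.38 ± 0.22 (adjusted p = 0.011) and -3.05 ± 0.24 (adjusted p = 0.000662) for the label SAIR1-YFP-OX2. All 4 calls held with any 1 library left out, except the one for SAIR1-YFP-OX2 under mock without Col-0 mock replicate 1 (adjusted p = 0.0526). A rule set in advance sought genes called lower in sair1-1 and higher in SAIR1-YFP-OX2 under both treatments, and lower in sair1-1 in the paired RNA-seq: 0 genes met it with the labels as given, and 1, SAIR1, with the RNA-seq labels exchanged. In the paired RNA-seq, and under mock for the label SAIR1-YFP-OX2, SAIR1 was the 1 gene called between genotypes. The rule could thus return no other gene, and it restates the SAIR1 level. Both directions of the SAIR1 change run against the names of the lines. Every direction between RNA-seq genotypes below is therefore given for the libraries labelled so, not for the line.

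In the flg22 experiment the order was the other way round. SAIR1 stood at 48.6 ± 3.01 CPM in Col-0 mock and 78.9 ± 27.5 CPM in Col-0 flg22 of the paired RNA-seq, against 1.97 ± 0.274 and 2.87 ± 0.707 CPM in sair1-1. The change was -4.62 ± 0.35 under mock (adjusted p = 0.00864) and -4.77 ± 0.35 under flg22 (adjusted p = 0.00625), and SAIR1 was the 1 gene called in either paired comparison of the genotypes. The fold stayed between -5.06 and -4.35 with any 1 library left out. The call was lost under mock without Col-0 replicate 2 (adjusted p = 0.0704), sair1-1 replicate 1 (0.184) or sair1-1 replicate 2 (0.125), and under flg22 without sair1-1 replicate 1 (0.285) or replicate 2 (0.183). In the Ribo-seq, SAIR1 had 194 counts in Col-0 mock and 0 in sair1-1 mock, at least 36.1-fold lower with a floor of 3 counts over the group, and 360 against 3 counts under flg22, a ratio of 165 (95% interval 56.2 to 806, counting error only). The Ribo-seq call under mock was lost without sair1-1 mock replicate 2 (adjusted p = 0.14).

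**Figure D1:**
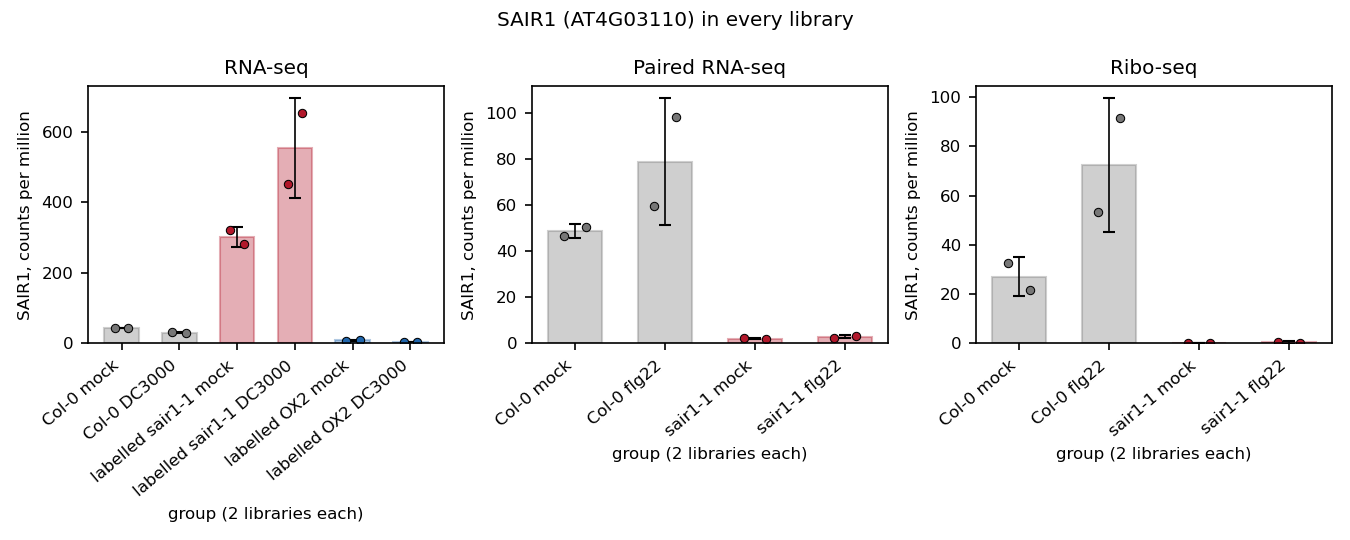
SAIR1 level (CPM) in each library of the 3 count tables, by genotype label and treatment, with bars for means, error bars for SD and points for libraries. The libraries labelled sair1-1 lie above Col-0 in the RNA-seq (301 CPM against 43.4 CPM under mock) and below it in the paired RNA-seq (1.97 CPM against 48.6 CPM).

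The DC3000 comparison in Col-0 asked how leaves changed over 24 h of infection. CYP94B3, an enzyme that breaks down jasmonoyl-isoleucine, went from 0.0473 ± 0.0669 to 113 ± 30.4 CPM, BSMT1, which makes methyl salicylate, from 0.124 to 387 ± 121 CPM, and TPS10 (AT2G24210), a monoterpene synthase, from 0 to 77.0 ± 2.28 CPM. The jasmonate (JA) repressor gene JAZ10 rose by 6.21 ± 0.30 (adjusted p = 2.84e-07), the salicylic acid (SA)-responsive glutaredoxin gene GRX480 by 6.59 ± 0.25 (1.25e-07), the PTI marker FRK1 by 3.94 ± 0.17 (2.2e-07) and CYP79B2, an entry enzyme of camalexin and indole glucosinolate synthesis, by 4.90 ± 0.22 (2.38e-07). The gibberellin-responsive gene GASA6 fell by 7.93 ± 0.34, the aldolase gene FBA5 by 7.67 ± 0.43, the expansin gene EXPA8 by 7.04 ± 0.22 and the gene of Rubisco activase, RCA, by 3.05 ± 0.32 (adjusted p at most 1.35e-05 for these 4). Of 20251 genes tested, 6791 rose and 6769 fell.

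Set by set, the Col-0 response to DC3000 moved hormone and defence genes up and photosynthesis genes down. All 26 JA pathway genes rose, with a median of 4.45 (camera adjusted p = 1.36e-21, or 0.0965 with an estimated correlation), and so did all 14 tryptophan, camalexin and indole glucosinolate genes, with a median of 4.06 (6.74e-13, or 0.144). Of 23 SA pathway genes 22 rose (median 2.46; 1.13e-08, or 0.238), and so did 10 of 10 PR and SA-marker protein genes (3.47; 3.08e-06, or 0.114). So did 21 of 27 early PTI genes with 4 falling (2.52; 6.14e-10, or 0.0965), 22 of 24 PTI receptors and kinases with 1 falling (1.26; 2.13e-08, or 0.238) and 13 of 14 genes of endoplasmic reticulum (ER) folding (1.75; 5.14e-06, or 0.284). All 41 nuclear photosynthesis genes fell (-2.03; 5.21e-12, or 0.417), as did 30 of 36 cytosolic ribosomal protein genes with 2 rising (-0.686; 0.00215, or 0.6) and 13 of 23 guard cell markers with 1 rising (-0.923; 0.0129, or 0.474). The call of each of these 10 lists held with any 1 library left out. Adjusted over the list alone the counts were the same, save for 31 falling ribosomal protein genes.

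The remaining 6 lists were not called in that comparison. Translation factors (4 up and 9 down of 21, median -0.297, camera adjusted p = 0.526), markers of other cell types (2 up and 10 down of 21, -0.796, 0.254), abscisic acid (ABA) response genes (10 up and 8 down of 19, 0.696, 0.961), heat shock proteins (5 up of 6, 1.44, 0.198) and clock genes (5 up and 3 down of 11, 0.734, 0.61) were those besides the plastid-encoded genes. Adjusted over the list alone these were 3 and 9, 2 and 7, 10 and 8, 5 and 0, and 6 and 3. Of 76 plastid-encoded genes 2 fell, 0 of them adjusted over the list alone, and the median (0.0307) and mean (0.0458) had the opposite sign to the test (down, adjusted p = 0.5).

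The response to DC3000 under the other labels moved the same marker genes. In the libraries labelled sair1-1, JAZ10 rose by 5.03 ± 0.29, GRX480 by 4.91 ± 0.23, CYP79B2 by 4.69 ± 0.22 and FRK1 by 2.88 ± 0.16. There FBA5 fell by 6.08 ± 0.39 and RCA by 2.33 ± 0.31 (adjusted p at most 0.000167 for these 6 changes). In those labelled SAIR1-YFP-OX2, JAZ10 rose by 6.46 ± 0.31, GRX480 by 6.33 ± 0.25, CYP79B2 by 4.79 ± 0.22 and FRK1 by 3.87 ± 0.17. There FBA5 fell by 8.44 ± 0.45 and RCA by 3.40 ± 0.32 (adjusted p at most 8.59e-06 for these 6 changes). The label sair1-1 had 4936 rising and 3991 falling genes, and 5627 in all without its DC3000 replicate 2. The label SAIR1-YFP-OX2 had 6245 rising and 6144 falling. Of the genes called in Col-0, 8450 were also called for the label sair1-1, 8448 of them in the same direction, and 11253 for the label SAIR1-YFP-OX2, 11246 in the same direction.

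Of the 10 lists called in Col-0, 9 were called for both labels. Ribosomal protein genes were not, with medians of -0.0485 (camera adjusted p = 0.677) for the label sair1-1 and -0.239 (0.194) for the label SAIR1-YFP-OX2. The JA pathway reached a median of 4.03 in the libraries labelled sair1-1 (26 of 26 up, camera adjusted p = 3.4e-33, or 0.0844 with an estimated correlation) and 4.49 in those labelled SAIR1-YFP-OX2 (26 of 26, 3.15e-23, or 0.149). The SA pathway reached 1.75 (20 of 23 up, 5.7e-07, or 0.331) and 2.45 (23 of 23, 1.03e-08, or 0.23). Early PTI genes reached 1.76 (19 up and 3 down of 27, 1.49e-11, or 0.0844) and 2.46 (21 up and 4 down, 1.55e-08, or 0.149), and photosynthesis genes -1.3 (36 of 41 down, 1.7e-11, or 0.487) and -2.27 (41 of 41, 4.54e-15, or 0.339). Adjusted over the list alone, the label sair1-1 had 26 JA pathway, 21 SA pathway and 20 rising early PTI genes and 39 falling photosynthesis genes. These 8 list calls held in each leave-out.

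**Figure D2:**
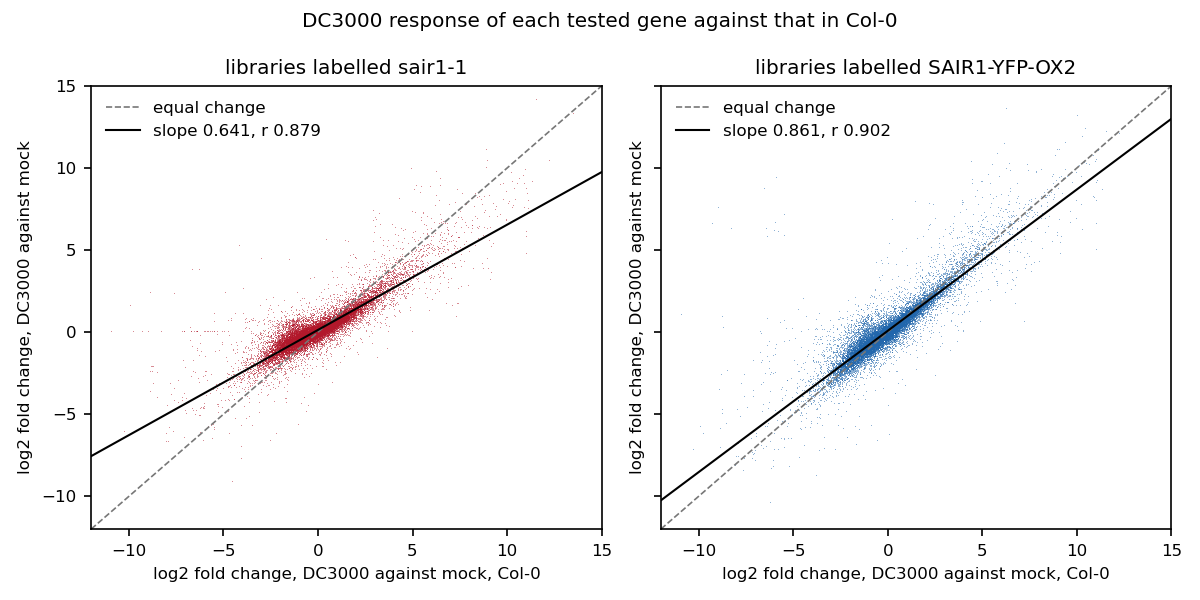
Log2 fold change from mock to DC3000 of each gene in Col-0 (horizontal axis) and in the libraries of the other label (vertical axis), 1 point per gene, with the fitted line (solid) and equal change (dashed). The slope across genes is 0.641 for the label sair1-1 and 0.861 for the label SAIR1-YFP-OX2.

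Without infection, the comparison of the libraries labelled sair1-1 with Col-0 asked which genes the genotype alters at rest. AT4G12500, which encodes a lipid transfer protein-like protein, was higher by 3.20 ± 0.30 (adjusted p = 0.00333), the ubiquitin ligase gene RING1 by 2.97 ± 0.28 (0.00333), the receptor-like kinase gene CRK23 by 2.51 ± 0.23 (0.00333) and AT1G13470 by 2.29 ± 0.23 (0.00428), all in the libraries labelled sair1-1. WRKY53, a transcription factor gene of defence and senescence, was higher by 1.55 ± 0.19 (0.0138), WRKY38 by 2.18 ± 0.33 (0.0311), FRK1 by 1.14 ± 0.17 (0.0306) and CYP82C2, a camalexin-related cytochrome P450 gene, by 4.65 ± 0.76 (0.0433). The guard cell gene GC1 (AT1G22690) was lower, at -1.51 ± 0.23 (0.031), as was EXPA8 at -0.83 ± 0.14 (0.0463). PR2, at 1.12 ± 0.26 (0.115), and EDS1, at 0.81 ± 0.19 (0.117), were not called. In all, 57 genes were called higher and 7 lower.

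The number of calls rested on single libraries. It was 8 without Col-0 mock replicate 1, 7 without labelled sair1-1 mock replicate 1 and 9 without replicate 2, against 59 without Col-0 mock replicate 2. SAIR1, AT4G12500, RING1 and CRK23 were among the called genes each time, CRK23 being named for this reason. AT1G13470 was lost without Col-0 mock replicate 1 (adjusted p = 0.0832), WRKY38, CYP82C2 and GC1 without any 1 of the 4 libraries (at most 0.307), WRKY53 (at most 0.187) and EXPA8 (at most 0.296) without each except Col-0 mock replicate 2, and FRK1 without each except labelled sair1-1 mock replicate 2 (at most 0.261). As sets, PR and SA-marker protein genes were higher in the libraries labelled sair1-1 (0 of 10 called, 6 adjusted over the list alone, median 1.02; camera adjusted p = 1.48e-10, or 0.0704 with an estimated correlation). So were the SA pathway (1 of 23 called, 7 adjusted over the list alone, 0.779; 2.74e-11, or 0.179), early PTI genes (2 of 27, 7 alone, 0.368; 4.86e-08, or 0.17), PTI receptors and kinases (0 of 24, 7 alone, 0.284; 4.58e-07, or 0.294) and ER folding genes (0 of 14, 7 alone, 0.443; 1.48e-10, or 0.179). Photosynthesis genes (0 of 41 and 0 alone, -0.396; 4.01e-08, or 0.611) and guard cell markers (1 of 23 lower, 5 alone, -0.356; 4.84e-07, or 0.179) were lower, and these 7 list calls held in each of the 4 leave-outs. Without Col-0 mock replicate 1 the SA pathway median was 0.482 and that of PTI receptors and kinases 0.151. Without Col-0 mock replicate 2 the latter was 0.43 and that of early PTI genes 0.568. Markers of other cell types were called lower too (0 of 21 and 0 alone, -0.175; 0.0172, or 0.294), lost without Col-0 mock replicate 1 or labelled sair1-1 mock replicate 1 (-0.103 and -0.0747; adjusted p at most 0.333). They were at -0.273 and -0.337 without the other replicate of either group. So were plastid-encoded genes (0 of 76 and 0 alone, -0.323; 0.00205, or 0.861), lost without labelled sair1-1 mock replicate 1 (-0.0968; adjusted p = 0.615) and at -0.513 without replicate 2.

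The libraries labelled sair1-1 were also compared with Col-0 under DC3000. The cell wall enzyme gene TCH4 was higher by 2.47 ± 0.25 (adjusted p = 0.00612), and so were the ribosomal protein genes RPS28 by 0.77 ± 0.12 (0.00906), RPS5B by 0.69 ± 0.12 (0.012) and RPL24A by 0.77 ± 0.14 (0.0121), and WRKY53 by 1.52 ± 0.20 (0.00776). EXL3, an EXORDIUM-like gene, was higher by 2.26 ± 0.44 (0.0149), while the auxin conjugate hydrolase gene ILL5 was lower, at -2.69 ± 0.58 (0.0201), as was the phosphate response gene SPX3 at -2.52 ± 0.75 (0.0436). The JA turnover gene CYP94C1 was lower, at -1.54 ± 0.29 (0.0133), as were JAZ8 at -1.17 ± 0.28 (0.0214), BSMT1 at -1.69 ± 0.38 (0.0214), the defensin gene PDF1.2 at -1.41 ± 0.29 (0.0156) and CYP79B3 at -1.45 ± 0.25 (0.0116). So were the SA synthesis gene EPS1 at -0.86 ± 0.16 (0.0121) and NCED3, the gene of the main ABA-forming dioxygenase, at -1.47 ± 0.29 (0.0147). In all, 2333 genes were called higher and 1893 lower. With the size factors of DESeq2 in the same fit these were 1894 and 2782, so which side holds more genes depends on the scaling.

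Those calls depended on a pair of libraries, Col-0 DC3000 replicate 1 and labelled sair1-1 DC3000 replicate 1, which held the highest nuclear rRNA shares (5.54% and 3.87%). Without Col-0 DC3000 replicate 1 the count fell from 4226 to 4 genes (AT3G09450, BT2, SAIR1 and AT4G16146), and without labelled sair1-1 DC3000 replicate 1 to 14, against 4200 and 4320 without either replicate 2. Of the genes just named, TCH4 was lost without Col-0 DC3000 replicate 1 (adjusted p = 0.0583), SPX3 without any 1 of the 4 libraries (at most 0.257) and the other 13 without either replicate 1 (at most 0.141), while their folds kept their sign. As sets, ribosomal protein genes were higher (26 of 36 called higher and 1 lower, 31 and 1 adjusted over the list alone, median 0.655; camera adjusted p = 3.22e-11, or 0.607 with an estimated correlation). The JA pathway (10 of 26 lower, 14 alone, -0.661; 1.91e-05, or 0.607) and tryptophan, camalexin and indole glucosinolate genes (8 of 14 lower, 9 alone, -0.715; 2.37e-05, or 0.607) were lower, and these 3 list calls held in each of the 4 leave-outs. Outside these 3, medians were 0.373 for photosynthesis genes, -0.413 for ABA response genes and -0.329 for PTI receptors and kinases.

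The difference between responses asked which genes respond to DC3000 otherwise than in Col-0. In the libraries labelled sair1-1, 134 genes had a more positive and 87 a more negative response than in Col-0. These were 52 and 88 with the size factors of DESeq2 and 115 and 139 without rRNA and organelle genes. EXPA8 differed by 2.22 ± 0.32 and the aquaporin gene DELTA-TIP by 2.25 ± 0.37, both falling less. AT4G12500 differed by -3.66 ± 0.38 (adjusted p = 0.0351), MAPKKK18, an ABA-induced kinase gene, by -2.90 ± 0.44, GRX480 by -1.68 ± 0.31, the chitin receptor gene LYK5 by -1.37 ± 0.26 and MYB51, a regulator of indole glucosinolates, by -1.52 ± 0.30 (adjusted p = 0.0482 for each of these except AT4G12500). For the 134 genes the median response was -1.98 in Col-0 and -0.672 in the libraries labelled sair1-1, and for the 87 genes 2.83 and 1.34. Against Col-0 the 134 genes had medians of -0.167 under mock and 1.12 under DC3000, and the 87 genes 0.894 and -0.645. These sets were chosen by that difference, so the medians only describe them. The count of 221 was 0 without any 1 of Col-0 DC3000 replicate 1, Col-0 mock replicate 1, labelled sair1-1 DC3000 replicate 1, mock replicate 1 or mock replicate 2. It was 2 without Col-0 mock replicate 2 (AT4G12500 and LHT1, so that the other 6 genes just named were lost there too, adjusted p at most 0.213), 1930 without Col-0 DC3000 replicate 2 and 1590 without labelled sair1-1 DC3000 replicate 2.

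As sets, the SA pathway responded less in the libraries labelled sair1-1 (0 of 23 called, 10 lower adjusted over the list alone, median -0.948; camera adjusted p = 6.31e-08, or 0.312 with an estimated correlation). So did PR and SA-marker protein genes (1 of 10 lower, 6 alone, -1.45; 5.46e-06, or 0.298), PTI receptors and kinases (1 of 24, 14 alone, -0.578; 1.34e-07, or 0.312), ER folding genes (0 of 14, 8 alone, -0.778; 5.14e-07, or 0.312) and early PTI genes (0 of 27, 6 lower and 1 higher alone, -0.755; 0.000114, or 0.312). Against Col-0 the SA pathway median was 0.779 under mock and -0.357 under DC3000, and the PR and SA-marker median 1.02 and -0.556. PTI receptors and kinases were at 0.284 and -0.329, ER folding genes at 0.443 and -0.259 and early PTI genes at 0.368 and -0.203. A higher mock level was thus part of each smaller response. Ribosomal protein genes (0 of 36, 19 higher and 1 lower alone, 0.614; 6.31e-08, or 0.312) and photosynthesis genes (0 of 41 and 0 alone, 0.776; 3.52e-07, or 0.414) had a more positive response. These 7 list calls held in each of the 8 leave-outs, and the photosynthesis median ranged from 0.397 to 1.18 over them. Without Col-0 DC3000 replicate 1 that median was 0.446, without replicate 2 1.18 and without labelled sair1-1 DC3000 replicate 1 0.397. Another 6 lists were called there, each lost in at least 1 leave-out. Markers of other cell types had a more positive response (0 of 21 and 0 alone, 0.793; 0.0153, or 0.312). That call was lost without Col-0 mock replicate 1 (0.458), labelled sair1-1 DC3000 replicate 2 or mock replicate 1 (adjusted p at most 0.0769). So had translation factors (0 of 21, 5 higher and 1 lower alone, 0.287; 0.0367, or 0.414), lost without Col-0 DC3000 replicate 2, Col-0 mock replicate 2 (0.185), labelled sair1-1 DC3000 replicate 2 or mock replicate 1 (adjusted p at most 0.114). A more negative response was called for JA pathway genes (0 of 26, 1 alone, -0.397; 0.00165, or 0.414) and tryptophan, camalexin and indole glucosinolate genes (1 of 14, 1 alone, -0.447; 0.004, or 0.414). Both calls were lost without Col-0 mock replicate 1 (medians -0.105 and -0.172; adjusted p 0.057 and 0.267). Without Col-0 mock replicate 2 the medians were -0.83 and -0.895, and the tryptophan median was -0.27 without labelled sair1-1 DC3000 replicate 1. ABA response genes (0 of 19 and 0 alone, -0.675; 0.0294, or 0.433) were lost without Col-0 mock replicate 1 (-0.377), labelled sair1-1 DC3000 replicate 1 (-0.432), mock replicate 1 or Col-0 DC3000 replicate 2 (adjusted p at most 0.185). Heat shock genes (0 of 6 and 0 alone, -0.705; 0.0274, or 0.414) were lost without Col-0 mock replicate 1 or labelled sair1-1 mock replicate 1 (-0.469; adjusted p at most 0.0578). They were at -1.28 without Col-0 mock replicate 2.

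Few genes were called between the libraries labelled SAIR1-YFP-OX2 and Col-0. Under mock, SAIR1 was the 1 gene called (897 genes at an unadjusted p under 0.05, 33 calls by DESeq2), with 0 calls without Col-0 mock replicate 1, 2 without Col-0 mock replicate 2 and 29 without SAIR1-YFP-OX2 mock replicate 1. Under DC3000, BT2, a BTB scaffold gene of the sugar and nitrogen response, was higher by 2.35 ± 0.18 (adjusted p = 0.000662), the RING finger gene AT5G22920 by 2.50 ± 0.18 (0.000662), AT3G15450 by 1.7 ± 0.14 (0.000767) and MEE14 by 2.05 ± 0.26 (0.0442), and SAIR1 was lower. These 5 were the calls, named after they were seen, against 144 without Col-0 DC3000 replicate 2, and MEE14 was lost without any 1 of the other 3 libraries (adjusted p at most 0.514). AT5G22920 was also the 1 gene whose response to DC3000 differed from Col-0, by 2.34 ± 0.24 (adjusted p = 0.0228), lost without any 1 of Col-0 DC3000 replicates 1 and 2, Col-0 mock replicate 2, SAIR1-YFP-OX2 DC3000 replicates 1 and 2 or mock replicate 2 (at most 0.138), and 12 genes were called without SAIR1-YFP-OX2 mock replicate 1.

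Among lists, early PTI genes were higher in the libraries labelled SAIR1-YFP-OX2 under mock (0 of 27 called and 0 adjusted over the list alone, median 0.272; camera adjusted p = 9.04e-05, or 0.532 with an estimated correlation) and ribosomal protein genes lower (0 of 36 and 0 alone, -0.174; 1.69e-06, or 0.532). In the response to DC3000, ribosomal protein genes moved up against Col-0 (0 of 36 and 0 alone, 0.354; 1.47e-08, or 0.603) and early PTI genes down (0 of 27 and 0 alone, -0.395; 0.000629, or 0.603). These 4 list calls held in each leave-out, but 3 medians moved. That of early PTI genes was 0.426 under mock without Col-0 mock replicate 2 and -0.219 in the response without Col-0 mock replicate 1. That of ribosomal protein genes in the response was 0.215 without Col-0 DC3000 replicate 1. Other lists moved by as much. With all libraries, the response of plastid-encoded genes differed from Col-0 by a median of -0.735, that of PR and SA-marker protein genes by -0.584 and that of ABA response genes by -0.4. Under DC3000 plastid-encoded genes were at -1.02 against Col-0.

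Both labels shared 4 called genes with the same direction against Col-0 under DC3000. The genes BT2, AT5G22920, AT3G15450 and MEE14 were called higher for both, where independent lists would share 0.461. Across genes, which are not independent replicates, the correlation of the 2 log2 fold changes was 0.454 under DC3000 and 0.286 under mock. Simulated unchanged groups against the same Col-0 libraries gave 0.49 to 0.561 and 0.454 to 0.555 over 100 draws. The covariance was 0.191 under DC3000, against 0.0996 to 0.124 in the simulations, and 0.101 under mock, against 0.0879 to 0.117. Both comparisons use the same Col-0 libraries, and the simulations drew each gene independently. Neither the shared calls nor the covariance can therefore separate a shared change from a shift of a Col-0 library. The count of 4 was 135 without Col-0 DC3000 replicate 2, 1 without Col-0 DC3000 replicate 1 and 2 without labelled sair1-1 DC3000 replicate 1.

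The flg22 experiment asked how 45 min of the peptide changes transcripts and their translation, with and without SAIR1. At the transcript level in Col-0, IOS1, a receptor kinase gene that primes PTI, rose by 3.43 ± 0.39 (adjusted p = 0.0426), the receptor kinase gene AT4G18250 by 3.26 ± 0.35 (0.0335) and AT3G46280 by 3.10 ± 0.28 (0.0185), and the linker histone gene HIS1-3 fell by 2.83 ± 0.27 (0.0209). AT2G36690 was the other of the 5 calls, named after it was seen. With replicates as blocks the calls were 120 up and 19 down, and without a low-count filter 138 genes were called. FRK1, at 3.94 ± 0.81 (0.112), the heat shock factor gene HSFA2, at 7.70 ± 1.06 (0.0661), and HSP90.1, at 4.55 ± 0.67 (0.0661), were not called without blocks. There were 39 calls without Col-0 flg22 replicate 1 and 0 without either Col-0 mock replicate; IOS1, AT4G18250 and HIS1-3 were lost without Col-0 flg22 replicate 2 too (adjusted p at most 0.326 over these leave-outs).

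In sair1-1, flg22 raised heat shock genes of the paired RNA-seq. HSFA2 rose by 7.49 ± 1.00 (adjusted p = 0.0276), HSP90.1 by 5.21 ± 0.69 (0.0268), HSP70 by 4.44 ± 0.70 (0.0419), HSP101 by 4.21 ± 0.71 (0.0499), CYP94C1 by 5.50 ± 0.77 (0.0312) and AT3G46280 by 4.81 ± 0.31 (0.00191). The phosphatase gene HAI1 fell by 4.50 ± 0.58 (0.0265), the malate channel gene ALMT1 by 3.64 ± 0.48 (0.0271), HIS1-3 by 3.02 ± 0.28 (0.013) and the stress gene RD29A by 1.85 ± 0.29 (0.0408). In all 75 genes rose and 16 fell, or 261 and 74 with replicates as blocks. The count of 91 fell to 25 without sair1-1 flg22 replicate 1, 54 without replicate 2, 21 without mock replicate 1 and 0 without mock replicate 2, so that none of these calls held in every leave-out (adjusted p at most 0.413). The fold of HSP101 was 2.45 without flg22 replicate 2. ABA response genes as a set had a median of -0.671 (2 of 18 lower, 3 up and 3 down alone; camera adjusted p = 0.00564, or 0.324 with an estimated correlation), lost without sair1-1 flg22 replicate 2 (-0.297; adjusted p = 0.156).

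Early PTI genes rose as a set with flg22 in both genotypes of the paired RNA-seq. In Col-0 the median was 1.49 (0 of 28 called, 17 adjusted over the list alone; camera adjusted p = 1.12e-14, or 0.23 with an estimated correlation), and in sair1-1 it was 1.02 (0 of 28, 11 alone; 2.18e-09, or 0.324), with 0.509 without sair1-1 mock replicate 2 and 1.57 without replicate 1. Heat shock proteins reached 3.91 in Col-0 (0 of 6, 5 alone; 1.12e-14, or 0.23) and 4.83 in sair1-1 (4 of 6, 6 alone; 1.2e-18, or 0.207), or 4.58 with genes at 0 in a group set to the floor. Tryptophan, camalexin and indole glucosinolate genes reached 1.33 in Col-0 (0 of 14, 8 alone; 5.21e-09, or 0.23) and 1.14 in sair1-1 (0 of 14, 6 alone; 2.18e-09, or 0.303), or 1.73 without sair1-1 mock replicate 1. The 6 list calls held in each leave-out. No gene differed in its flg22 response between the genotypes by edgeR (195 genes at an unadjusted p under 0.05, 1 call by DESeq2), with 0 calls in each of the 8 leave-outs as well.

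Between genotypes of the paired RNA-seq, several lists were called under mock and no single gene except SAIR1. PR and SA-marker protein genes were lower in sair1-1, with a median of -1.23 (0 of 10 called, 1 adjusted over the list alone; camera adjusted p = 0.00013, or 0.34 with an estimated correlation). That call was lost without Col-0 mock replicate 2, the library with PR1 at 246 CPM against 1.47 CPM in replicate 1, or sair1-1 mock replicate 1 (medians -0.289 and -0.749; adjusted p at most 0.668). It was -2.56 without sair1-1 mock replicate 2. Under flg22 the median was -1.21 (0 of 10 and 0 alone; 5.81e-06, or 0.463), held in each leave-out. JA pathway genes had a median of -0.66 (0 of 25, 4 alone; 3.13e-12, or 0.34) and tryptophan, camalexin and indole glucosinolate genes one of -0.552 (0 of 14, 2 alone; 3.36e-09, or 0.34). JAZ8 was at -5.01 ± 0.93, CYP94C1 at -3.18 ± 0.70 and the camalexin gene PAD3 at -3.74 ± 0.85 (adjusted p = 1 for each, not called). Under flg22 the medians of both lists were -0.352 (2.86e-05, or 0.807; lost without Col-0 flg22 replicate 1 or sair1-1 flg22 replicate 2, adjusted p at most 0.685, with medians of 0.00316 and 0.0388, and -0.599 without Col-0 flg22 replicate 2 and -1.27 without sair1-1 flg22 replicate 1) and -0.693 (1.53e-07, or 0.463), with 0 calls in either list, 0 adjusted over the list alone. The other 3 calls of these 2 lists held in each of the 4 leave-outs; under mock the tryptophan median was -0.296 without Col-0 mock replicate 2 and the JA median -0.414 without replicate 1. Called higher were guard cell markers (0.308 under mock; 0.0142, or 0.794; and 0.14 under flg22; 0.021, or 0.839). Under mock the call was lost without Col-0 replicate 1 (0.181) or sair1-1 replicate 2 (0.17; adjusted p at most 0.463), with 0.504 without Col-0 replicate 2. Under flg22 it was lost without Col-0 replicate 1 or sair1-1 replicate 2 (both medians under 0, -0.199 in the second case, adjusted p at most 0.627), with 0.68 and 0.381 without the others. ABA response genes were called higher under mock (0.22; 0.0142, or 0.34) and photosynthesis genes under flg22 (0.532; 2.55e-14, or 0.807). The first was lost without Col-0 mock replicate 2 (0.403; adjusted p = 0.0954), the other without Col-0 flg22 replicate 1 (0.2; adjusted p = 0.0963). Photosynthesis genes were at 1.07 without Col-0 flg22 replicate 2 and 0.162 without sair1-1 flg22 replicate 1.

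Ribosome footprints of immune signalling genes rose with flg22. In Col-0, CYP81F2, an indole glucosinolate enzyme gene, rose by 3.02 ± 0.21 (adjusted p = 8.49e-09), RBOHD, the gene of the oxidase behind the PTI oxidative burst, by 2.76 ± 0.18 (4.79e-09), WRKY11 by 2.91 ± 0.27 (2.28e-07), the ubiquitin ligase gene PUB22 by 4.73 ± 0.46 (7.34e-07) and the kinase gene MPK3 by 1.94 ± 0.19 (4.96e-07). LOX4, a lipoxygenase gene of JA synthesis, rose by 3.86 ± 0.32 (1.81e-06), PAD4, an immune regulator gene, by 3.35 ± 0.39 (3.98e-06), HSP90.1 by 2.24 ± 0.26 (9.21e-06) and the glutathione transferase gene GSTF6 by 1.93 ± 0.22 (3.24e-06). PDF1A, the gene of a peptide deformylase, fell by 4.41 ± 0.70 (0.00021). AT1G07160, AT2G36690 and CYP82C3 went from 0 to 59.1 ± 3.79, 88.8 ± 33.1 and 41.2 ± 5.87 CPM. In all 888 genes rose and 299 fell of 15391 tested, with 761 calls without Col-0 flg22 replicate 2 and 729 without Col-0 mock replicate 2.

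Of the 13 genes just named, 12 were also called up in the footprints of sair1-1, and PDF1A, at -1.23 ± 0.54 (adjusted p = 0.272), was not called. CYP81F2 rose by 2.45 ± 0.20 (adjusted p = 2.32e-07), RBOHD by 2.33 ± 0.18 (1.49e-07), WRKY11 by 2.73 ± 0.27 (1.61e-06), LOX4 by 2.7 ± 0.31 (8.09e-05), PAD4 by 2.97 ± 0.42 (9.03e-05), HSP90.1 by 2.66 ± 0.27 (3.04e-06), GSTF6 by 1.65 ± 0.22 (4.89e-05) and MPK3 by 0.99 ± 0.19 (0.00186, or 0.0683 without sair1-1 mock replicate 1). The cell wall enzyme gene XTH15 fell by 3.09 ± 0.33 (3.14e-06). In all 516 genes rose and 117 fell, with 327 calls without sair1-1 mock replicate 1 and 413 without replicate 2. Both genotypes shared 474 called genes, 473 of them in the same direction.

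PTI receptors and kinases rose in the footprints of both genotypes, and these were the calls that held with an estimated correlation. In Col-0 the median was 1.08 (12 of 24 up, 19 adjusted over the list alone; camera adjusted p = 1.91e-13, or 0.0176 with an estimated correlation), and in sair1-1 it was 0.866 (6 of 24, 15 alone; 1.51e-10, or 0.0277). Early PTI genes reached 2.26 in Col-0 (19 of 26, 23 alone; 1.79e-38, or 0.0516) and 1.2 in sair1-1 (11 of 26, 15 alone; 8.02e-17, or 0.132), and heat shock proteins 2.53 (5 of 9, 6 alone; 2.97e-08, or 0.0957) and 2.32 (5 of 9, 5 alone; 3.4e-08, or 0.132), the latter 2.23 with genes at 0 in a group set to the floor. The SA pathway reached 1.13 in Col-0 (8 of 18, 11 alone; 6.6e-08, or 0.0957), JA pathway genes 1.37 (11 of 26, 13 alone; 1.85e-12, or 0.156) and tryptophan, camalexin and indole glucosinolate genes 0.803 (5 of 13, 7 alone; 4.22e-06, or 0.0722). Ribosomal protein genes went down in Col-0 (1 of 37 called lower, 1 up and 10 down alone, -0.553; 0.000261, or 0.332), or -0.328 without Col-0 mock replicate 2. The 10 list calls of these sentences held in each of their 4 leave-outs. The heat shock median of Col-0 was 1.66 without flg22 replicate 1 and its JA median 0.881 without mock replicate 2. In sair1-1 the SA pathway reached 0.742 (4 up and 1 down of 18, 6 and 2 alone; 0.000625, or 0.272), or 0.457 without mock replicate 1. Tryptophan, camalexin and indole glucosinolate genes reached 0.89 there (4 of 13, 5 alone; 0.000639, or 0.132), or 0.464 without flg22 replicate 1 and 0.386 without mock replicate 2. Both calls held. JA pathway genes reached 0.48 (7 of 26, 8 alone; 0.000639, or 0.58), or 0.748 without sair1-1 flg22 replicate 2, and were lost without flg22 replicate 1 (-0.136; adjusted p = 0.183).

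**Figure D3:**
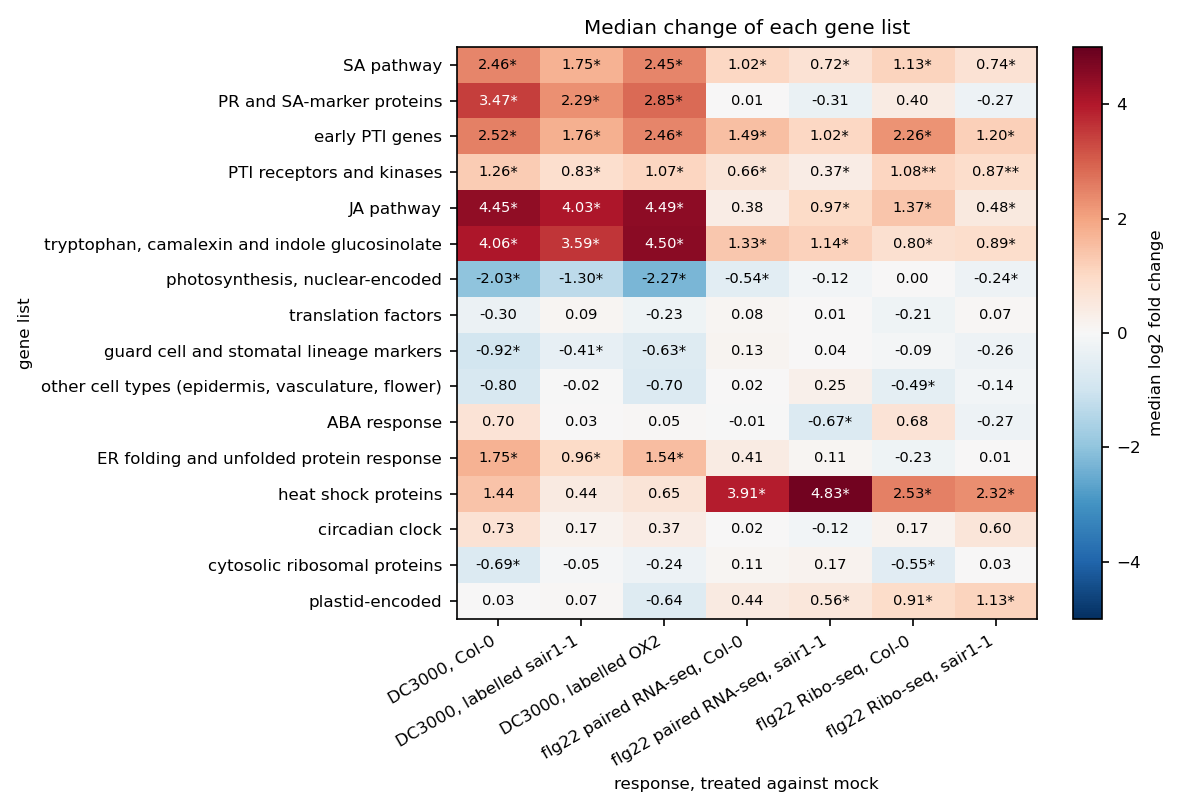
Median log2 fold change of the genes of each list (vertical axis) in each response to DC3000 or flg22 (horizontal axis), as coloured cells with 1 star for a camera adjusted p under 0.05 and a pair of stars where the call also held with an estimated correlation. A pair of stars stands at PTI receptors and kinases under flg22 in the Ribo-seq, at 1.08 in Col-0 and 0.866 in sair1-1.

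Between genotypes, footprints of AT3G12915, a gene of the elongation factor 2 family, were lower in sair1-1, along with those of SAIR1. AT3G12915 stood at 233 ± 48.7 CPM in Col-0 mock and 35.4 ± 8.9 CPM in sair1-1 mock, a change of -2.73 ± 0.31 (adjusted p = 0.000298, or 0.115 without sair1-1 mock replicate 2), and at 114 ± 21.3 and 7.6 ± 3.32 CPM under flg22, a change of -3.94 ± 0.34 (3.19e-06). Its transcripts in the paired RNA-seq changed by -0.47 ± 0.35 under mock and -0.71 ± 0.35 under flg22 (adjusted p = 1 for both), and its translational efficiency, footprints against transcripts, by -2.24 ± 0.47 (0.497) and -3.20 ± 0.50 (0.104), neither called. SAIR1 and AT3G12915 were the 2 calls under mock, named after they were seen, with 26 calls without Col-0 mock replicate 1 and 0 without sair1-1 mock replicate 2.

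After flg22, footprints of MPK3 and SZF1 were among those lower in sair1-1. MPK3, the gene of a kinase of the PTI cascade, stood at 954 ± 82.9 CPM in Col-0 and 440 ± 28.6 CPM in sair1-1, a change of -1.12 ± 0.18 (adjusted p = 0.0224), while its mock levels were 249 ± 19.9 and 221 ± 12.1 CPM. SZF1, a zinc finger gene that restrains immune transcripts, was at -1.25 ± 0.22 (0.0329), ERD7 at -1.52 ± 0.28 (0.0456), AT1G13930 at -1.60 ± 0.24 (0.0106) and ATCG00190, the plastid gene of an RNA polymerase subunit, at -2.55 ± 0.36 (0.0275). The receptor kinase gene AT5G56040 was higher, at 1.82 ± 0.31 (0.0246), as were the expansin gene EXPA1 at 1.81 ± 0.34 (0.0456) and AT4G34950 at 1.04 ± 0.19 (0.0456). WRKY33 at -1.10 ± 0.23 (0.105) and the JA synthesis gene AOS at -1.02 ± 0.22 (0.118) were not called. Including SAIR1 and AT3G12915, 3 genes were higher and 7 lower (2 and 9 with the size factors of DESeq2), with 4 calls without Col-0 flg22 replicate 1, 192 without sair1-1 flg22 replicate 1 and 3 without sair1-1 flg22 replicate 2.

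Of these calls, AT5G56040, EXPA1, AT4G34950, ERD7, SZF1 and MPK3 were lost without either Col-0 flg22 replicate or sair1-1 flg22 replicate 2 (adjusted p at most 0.631), ATCG00190 without sair1-1 flg22 replicate 2 (0.0647) and AT1G13930 without Col-0 flg22 replicate 2 (0.0627). WRKY33 and AOS were called without sair1-1 flg22 replicate 1. Early PTI genes as a set were lower in sair1-1 after flg22 (0 of 26 called, 3 lower adjusted over the list alone, median -0.602; camera adjusted p = 5.93e-11, or 0.259 with an estimated correlation), held in each of 4 leave-outs with medians from -1.06 to -0.393. In the paired RNA-seq the median of this list was -0.341 in the same comparison, so the lower footprints cannot be put down to translation alone.

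**Figure D4:**
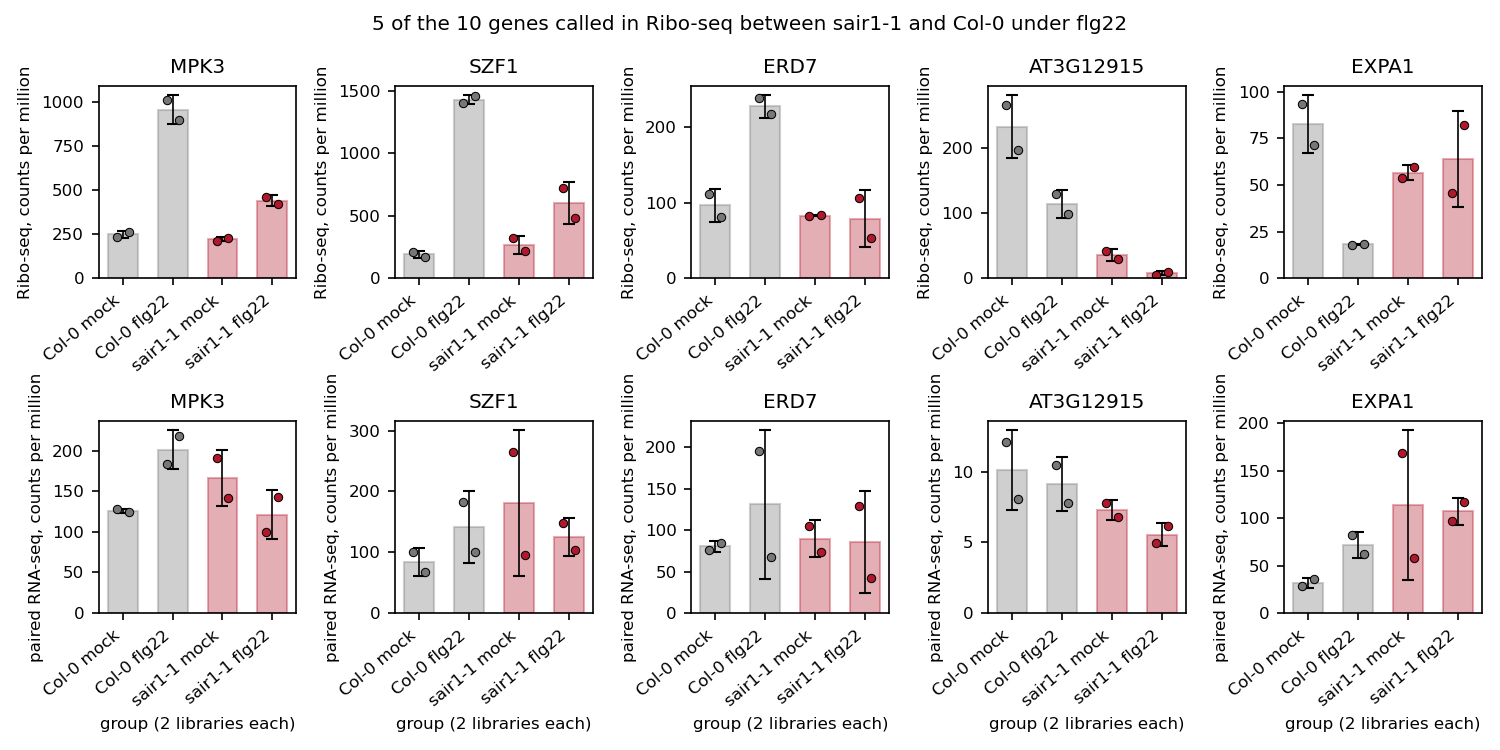
Levels (CPM) of MPK3, SZF1, ERD7, AT3G12915 and EXPA1 by genotype and treatment, in the Ribo-seq (top) and the paired RNA-seq (bottom), with bars for means, error bars for SD and points for libraries. MPK3 footprints under flg22 stand at 954 CPM in Col-0 and 440 CPM in sair1-1.

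The flg22 response of footprints was also tested for a difference between the genotypes. No gene was called by edgeR (1184 at an unadjusted p under 0.05, 22 calls by DESeq2), and WRKY33, at -1.80 ± 0.33 (adjusted p = 0.2), MPK3, at -0.94 ± 0.26 (0.412), and the syntaxin gene SYP122, at -1.45 ± 0.37 (0.38), stayed above the threshold. There were 85 calls without Col-0 mock replicate 1, 152 without sair1-1 flg22 replicate 1 and 1 without Col-0 flg22 replicate 2. WRKY33 was called in the first and second of these cases, SYP122 in the second. Early PTI genes responded less as a set in sair1-1 (0 of 26 called, 7 lower adjusted over the list alone, median -0.835, or -0.874 with genes at 0 in a group set to the floor; camera adjusted p = 1.21e-11, or 0.293 with an estimated correlation), and so did JA pathway genes (0 of 26 and 0 alone, -0.857; 1.37e-06, or 0.293). Ribosomal protein genes had a more positive response (0 of 37 and 0 alone, 0.592; 7.27e-05, or 0.293), with medians of -0.553 in Col-0 and 0.0292 in sair1-1. The 3 list calls held in each of the 8 leave-outs, with medians from -1.35 to -0.549, from -1.32 to -0.493 and from 0.355 to 0.697. At the transcript level the medians of this difference were -0.339 for early PTI genes, 0.194 for JA pathway genes and 0.0634 for ribosomal protein genes.

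Translational efficiency compares groups, since the labels do not state that the libraries of both kinds came from the same plants. It changed for few single genes. In Col-0, flg22 lowered that of PDF1A by 4.51 ± 0.65, of IAGLU, the gene of an auxin glucosyltransferase, by 2.94 ± 0.46 and of IQD24, a gene of a calmodulin-binding protein whose flg22 footprints were at 0 (adjusted p = 0.0354 for each), and edgeR called no gene higher. By DESeq2 50 genes were higher and 56 lower, without a low-count filter 159 and 140, and with a replicate block 2 and 4 (6 calls). Replicates blocked by sample left 0 calls. PDF1A, IAGLU and IQD24 were named after they were seen, with 0 calls without Ribo-seq Col-0 flg22 replicate 1, Col-0 mock replicate 2 or either paired RNA-seq Col-0 mock replicate, 1 without paired RNA-seq Col-0 flg22 replicate 1 and 21 without replicate 2. Each of the 3 was lost in 6 of 8 leave-outs (adjusted p at most 0.247). JAZ10 at 3.44 ± 1.05 (0.289), MPK3 at 1.26 ± 0.37 (0.279) and HSP90.1 at -2.32 ± 0.69 (0.279) were not called. In the other comparisons edgeR called 0 genes: flg22 in sair1-1 (975 at an unadjusted p under 0.05, 53 by DESeq2), sair1-1 against Col-0 under mock (698 and 11) and under flg22 (801 and 3) and the difference of responses (856 and 11). A leave-out gave 1 to 2 calls in 6 cases, namely Ribo-seq sair1-1 flg22 replicate 2 and paired RNA-seq sair1-1 mock replicate 2 for flg22 in sair1-1 (1 and 2), paired RNA-seq Col-0 mock replicate 1 under mock (2), Ribo-seq Col-0 flg22 replicate 2 under flg22 (1) and that library or paired RNA-seq Col-0 flg22 replicate 1 for the difference (1 each).

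As sets, early PTI genes gained translational efficiency with flg22 in Col-0 (0 of 26 called and 0 adjusted over the list alone, median 1.16; camera adjusted p = 1.85e-07, or 0.576 with an estimated correlation), and so did JA pathway genes (0 of 25 and 0 alone, 0.841; 3.24e-05, or 0.576; 0.46 and 1.31 without paired RNA-seq Col-0 flg22 replicates 2 and 1, 0.488 without Ribo-seq Col-0 mock replicate 2). Ribosomal protein genes lost it (0 of 37 and 0 alone, -0.655; 0.000205, or 0.576). Under mock, JA pathway genes had more in sair1-1 than in Col-0 (0 of 25, 4 alone, 0.938; 5.94e-10, or 0.412; 1.47 and 0.552 without Ribo-seq Col-0 mock replicates 1 and 2). Under flg22, photosynthesis genes had less (0 of 41 and 0 alone, -0.681; 5.9e-13, or 0.833; -0.435 and -1.2 without paired RNA-seq Col-0 flg22 replicates 1 and 2, -0.3 without sair1-1 flg22 replicate 1). The 5 list calls held in each of their 8 leave-outs. Heat shock proteins lost translational efficiency with flg22, by a larger median. In Col-0 it was -1.86 (0 of 6, 1 alone; 0.0313, or 0.576). That call was lost without Ribo-seq Col-0 flg22 replicate 2 (-1.43), Ribo-seq Col-0 mock replicate 2 (-0.375), paired RNA-seq Col-0 flg22 replicate 2 or mock replicate 1 (-1.33; adjusted p at most 0.292). In sair1-1 it was -2.41, or -2.29 at the floor (0 of 6, 4 alone; 0.000132, or 0.754), lost without paired RNA-seq sair1-1 flg22 replicate 2 (-1.06; adjusted p = 0.099). Early PTI genes in sair1-1 were at 0.232, or 0.128 at the floor (adjusted p = 0.364, not called).

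The RIP-seq asked which transcripts SAIR1 binds after flg22. Genes were ordered by the sum of their score ranks in both lists, in which the first were EXT3 (AT1G21310), an extensin gene of the cell wall, on chromosome 1 at 7453251 to 7453300 and 7453451 to 7453500 (scores 365 and 598), and FBA6 (AT2G36460), a cytosolic aldolase gene, on chromosome 2 at 15296801 to 15296850 in both (408 and 322). They were followed by the plastid gene PSBB (253.25 and 679), DI19 (602 and 287), AT3G28940 (404 and 254), UBC8 (286 and 303), the chaperone gene HSC70-1 (298 and 250), ECS1 (342 and 226), the actin gene ACT7 (215 and 310) and the mitochondrial gene ATMG00060 (224 and 242). SAIR1 itself had a peak in both (156 and 54), on opposite strands. The precipitated line overexpresses SAIR1 by its name, and the peaks were not tested against its input. They therefore do not show that SAIR1 binds its own transcript. With at least 1 bp on the same strand, 206 of 631 peaks (32.6%) of the first list met a peak of the second and 207 of 670 (30.9%) the reverse, against a mean of 18.9 (11 to 28 over 100 draws) with peaks moved within their genes. Those placements ran over the whole gene, introns included, so overlap above them is no test of binding. Among peaks with a gene, each list held 1 per gene, for 630 and 669 genes. The peak overlap thus tells only whether the listed places coincided, not how many genes the lists shared.

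The genes with a peak in both lists numbered 519, 463 of them nuclear, 47 plastid and 9 mitochondrial, without regard to strand. Random lists of like paired RNA-seq level held a mean of 0.788 tryptophan, camalexin and indole glucosinolate genes. With 6 of 14 (GSTF6, ASB1, PAD3, TSA1, ASA1 and TSB1), these genes were among the 519 more often. So were ribosomal protein genes (9 of 37 against 1.44) and plastid-encoded genes (38 of 70 against 0.866; for these 3 lists a one-sided permutation p of 1e-04, the smallest that 10000 lists can give, adjusted 0.000533), and translation factors (6 of 21, EEF1A1, LOS1, EIF4A1, PAB2, TBF1 and EEF1A4, against 1.74; permutation p = 0.0028, adjusted 0.0112). TBF1 is a heat shock factor that the fixed list held and which was kept. Without it 5 of 20 had a peak in both (adjusted permutation p = 0.0752, not called). Of PTI receptors and kinases 3 of 24 had one (CPK6, MPK4 and CPK5; adjusted permutation p = 0.62), of JA pathway genes 1 (AOS), and of early PTI, SA pathway and PR genes 0. Peaks of both lists lay on the same strand in 340 of the 519 genes, a count added after the data were seen. Of these, 3 were tryptophan, camalexin and indole glucosinolate genes (PAD3, ASA1 and TSB1; permutation p = 0.0105, adjusted 0.0656), 4 ribosomal protein genes (adjusted 0.0656) and 4 translation factors with TBF1 (adjusted 0.0688, or 0.374 for 3 without it), none of these lists called. The 24 plastid-encoded genes among them were more than in random lists (mean 0.556, adjusted permutation p = 0.0016). The random lists were matched on the mean paired RNA-seq level of Col-0 and sair1-1, mock and flg22, not on the input of SAIR1-YFP-OX2. Tryptophan, camalexin and indole glucosinolate genes had high footprints against that level. Their median log2 ratio was 1.02 in Col-0 flg22 (percentile 99.7) and 1.61 in sair1-1 flg22 (percentile 100). The match may thus not hold for that list. In the paired RNA-seq plastid reads made up 0.0332% to 0.111%, against 0.832% to 2.57% in the Ribo-seq. The plastid-encoded genes were thus compared with genes of a low level in the paired RNA-seq.

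Transcripts and footprints of these genes rose a little with flg22 against other genes, while their translational efficiency was not called in any of 5 comparisons by camera (adjusted p from 0.245 to 0.986). Against 10000 random lists of like level it lay apart in 3 of the 5. For flg22 in Col-0 the median was -0.0336 against 0.098 (percentile 0). It was 0.0274 against -0.1 for sair1-1 against Col-0 under flg22 (percentile 100) and 0.0238 against -0.132 for the difference of responses (percentile 100). In the genotype comparison under flg22, footprints were at percentile 43.8 (-0.0506 against -0.0466) and transcripts at percentile 0 (-0.0503 against 0.0687). Against the random lists, the higher translational efficiency there thus came with lower transcripts, not with more footprints. By camera neither was called there (adjusted p = 0.986 for translational efficiency and 0.119 for transcripts). Other genes had a median translational efficiency of 0.0432 there, above that of these genes. For the difference of responses, footprints were at percentile 100 and transcripts at 80. The random lists take genes as independent. With flg22, footprints had a median of 0.118 in Col-0 (70 up and 9 down of 455; camera adjusted p = 0.0013, or 0.11 with an estimated correlation) and 0.197 in sair1-1 (55 up and 3 down; 0.00016, or 0.11). In the paired RNA-seq the median was 0.146 in Col-0 (0.00723, or 0.238) and 0.239 in sair1-1 (4.84e-05, or 0.11), and in sair1-1 against Col-0 under mock it was -0.119 (4.84e-05, or 0.11).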

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

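Of the tests on the SAIR1 level, the count of libraries and the paired RNA-seq fold were chosen after the result was seen. So were the uniformly weaker response, the removal of rRNA and organelle genes and leaving out both DC3000 libraries with the highest rRNA share among the tests on DC3000. The SAIR1 level in the RNA-seq goes against the labels. Labels of sair1-1 and SAIR1-YFP-OX2 exchanged in the RNA-seq would place all libraries of both groups on the other side of Col-0. There lay 8 of 8, a count that restates the pattern. Under mock, the SAIR1 change was 2.79 for the label sair1-1 and -2.38 for the label SAIR1-YFP-OX2. In the paired RNA-seq it was -4.62 for sair1-1. For the SAIR1 transcript these values argue against the labels as given, while exchanged labels cannot be told apart from other reasons. A raised SAIR1 transcript in the sair1-1 line itself does not match the paired RNA-seq, where the line is at -4.62. Through other genes alone, exchanged labels cannot be told apart from labels as given. SAIR1 was the 1 gene called in the paired comparison under mock, so the other genes gave little to compare. The correlation across 17987 genes with the paired RNA-seq change differed by 0.106 (-0.09 for the label sair1-1, 0.0164 for the label SAIR1-YFP-OX2). With a library left out that difference ran from -0.0191 to 0.162, and the requirement that it hold in each leave-out, also for the count of libraries, was added after it was seen.

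The response to DC3000 was called different from Col-0 in 221 genes for the libraries labelled sair1-1. For those labelled SAIR1-YFP-OX2 it was called different in 1 gene. Both counts depended on single libraries, as described above. If the RNA-seq labels are exchanged, the 221 genes would belong to the overexpression line. A single atypical library cannot be told apart from a difference between groups: of 4226 genes called under DC3000, 4 were left without Col-0 replicate 1 and 14 without labelled sair1-1 replicate 1, each leave-out leaves a group of 1 library, and folds kept their sign, from 1.76 to 3.24 for EXL3, from -3.99 to -1.94 for ILL5, and from 2.32 to 2.61 for TCH4. That 1 leave-out alone must end the calls was required after these counts were seen. Reads of rRNA and organelle genes themselves do not account for the calls, since 4695 genes were called without those genes (2239 higher and 2456 lower, against 2333 and 1893). Without both DC3000 libraries with the highest rRNA share few calls were left, but Col-0 DC3000 and labelled sair1-1 DC3000 then held 1 library each. Leaving out both replicate 2 libraries was not run for comparison. The state of the libraries with the highest rRNA share therefore stays open. A uniformly weaker response cannot be told apart from an uneven one, with slopes against the response in the libraries labelled SAIR1-YFP-OX2 of 0.746 for rising and 0.624 for falling genes, a difference of 0.121 (0.0391 to 0.201 over 8 leave-outs).

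The test on RIP-seq abundance was set before the result was seen. The genes with a peak in both lists lie at a median percentile of 88.5 in mean paired RNA-seq CPM, with the lowest decile at 27.8. That peaks follow RNA abundance may therefore be part of the signal, while specific binding was not tested against the input.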

How the results depend on the processing

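With n = 2 per group and the Ribo-seq at 1.49 M to 4.78 M counts, small changes escape: in simulated data 2-fold changes were recovered for 3% of genes in the paired RNA-seq and 6% in the Ribo-seq. Leaving out a library moved 63 of 146 counts by more than 1.5 times, DESeq2 18 of 25, no low-count filter 15 of 25, the replicate block 8 of 25, size factors of DESeq2 2 of 26 and nuclear genes only 1 of 25. No named gene reversed with another scaling, filter, tool or block, and no called list with another scaling or block. With a library left out the medians of 10 called lists changed sign, as did that of plastid-encoded genes for DC3000 in Col-0 (-1.27 to 0.694, not called). Of 149 gene changes, 146 kept their side of the threshold with the size factors of DESeq2, 133 with the DESeq2 test, 133 without a filter and 130 with the replicate block. An estimated correlation kept 2 of 160 list calls, and size factors of DESeq2 159. Peak overlap stayed within 1.5 times, at 200 with reciprocal overlap of 50% and 241 without regard to strand (206). The cause was not tested for any value below, except that leave-outs and the upper part of the peak lists by score hold fewer data by construction. A peak midpoint in an exon, 5-mers and 7-mers were not run.

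Without a low-count filter, the libraries labelled sair1-1 differed from Col-0 in 192 genes under mock (64 with it) and in 749 responses to DC3000 (221), and those labelled SAIR1-YFP-OX2 in 8 genes under DC3000 (5) and 3 responses (1). Transcripts moved with flg22 for 138 genes in Col-0 (5) and 279 in sair1-1 (91). Footprints moved with flg22 for 961 in sair1-1 (633), and differed between genotypes for 13 under mock (2), 83 under flg22 (10) and 93 in the response (0). Translational efficiency had 299 calls for flg22 in Col-0 (3), 125 in sair1-1 (0), 77 between genotypes under mock (0), 53 under flg22 (0) and 52 in the response (0).

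By DESeq2, the RNA-seq counts were 390 for the label sair1-1 under mock (64), 2051 for its response (221), and 33 under mock (1), 29 under DC3000 (5) and 8 for the response (1) of the label SAIR1-YFP-OX2, with 17 shared genes (4). Paired RNA-seq counts were 705 and 790 for flg22 in Col-0 and sair1-1 (5 and 91), and 30 under mock (1), 8 under flg22 (1) and 1 in the response (0) between genotypes. Ribo-seq counts between genotypes were 33 under flg22 (10) and 22 in the response (0). Translational efficiency had 106 and 53 calls for flg22 in Col-0 and sair1-1 (3 and 0), 11 under mock (0), 3 under flg22 (0) and 11 in the response (0).

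With a replicate block, the label sair1-1 had 16 calls under mock and 0 in the response, and the label SAIR1-YFP-OX2 0 in the response. Flg22 moved 139 transcripts in Col-0 and 335 in sair1-1. Footprints differed for 17 genes under flg22 and 1 response, and translational efficiency had 6 calls in Col-0. The block changed no list call out of 25. Replicates blocked by sample gave translational efficiency 0 calls for flg22 in Col-0, 2 under mock and 1 under flg22 between genotypes.

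Without rRNA and organelle genes, chosen after the data were seen, the label sair1-1 had 112 calls under mock and the label SAIR1-YFP-OX2 3 responses, as with nuclear genes only (3) and size factors of DESeq2 (3), which left 140 responses for the label sair1-1. Without both DC3000 libraries with the highest rRNA share, also chosen afterwards, 3 genes under DC3000, 0 responses and 1 shared gene were called for the label sair1-1. In the RIP-seq, the upper 50% by score shared 99 peaks (206 in all) and a peak in either list gave 780 genes (519), and peaks of both lists on the same strand, chosen after the data were seen, 340. Calls of these genes among translation comparisons went from 5 to 0 with an estimated correlation, and list calls from 160 to 2. By fry, which tests the genes against no change and not against other genes, 3 translation comparisons were called.

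With 1 library left out, RNA-seq counts ranged from 5627 to 8418 for DC3000 in the label sair1-1 (8927), and between that label and Col-0 from 7 to 59 under mock, 4 to 4320 under DC3000 and 0 to 1930 in the response. For the label SAIR1-YFP-OX2 they ranged from 0 to 29, 4 to 144 and 0 to 12, and shared genes from 1 to 135. Paired RNA-seq counts ranged from 0 to 39 and 0 to 54 for flg22 in Col-0 and sair1-1, and from 0 to 2 between genotypes under mock and under flg22. Ribo-seq counts ranged from 729 to 1056 and 327 to 717 for flg22, and between genotypes from 0 to 26 under mock, 3 to 192 under flg22 and 0 to 152 in the response. Translational efficiency ranged from 0 to 21 and 0 to 2 for flg22 in Col-0 and sair1-1, and from 0 to 2 under mock, 0 to 1 under flg22 and 0 to 1 in the response.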

Other observations

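PR1, the SA marker gene AT2G14610, was uneven between libraries of untreated Col-0. In the paired RNA-seq its Col-0 mock libraries held 1.47 and 246 CPM, and Col-0 flg22 held 10.1 ± 8.34 CPM, sair1-1 mock 0.47 ± 0.306 CPM and sair1-1 flg22 1.55 ± 0.349 CPM. In the Ribo-seq the same groups held 982 ± 423, 1350 ± 154, 1160 ± 544 and 810 ± 130 CPM. In the RNA-seq PR1 stood at 393 ± 189 CPM in Col-0 mock and 2790 ± 687 CPM in Col-0 DC3000, at 756 ± 147 and 4900 ± 1360 CPM in the libraries labelled sair1-1 and at 516 ± 253 and 2370 ± 292 CPM in those labelled SAIR1-YFP-OX2. Between replicates of Col-0 mock PR1 differed 167-fold in the paired RNA-seq and 1.88-fold in the Ribo-seq.

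Footprints against transcripts in Col-0 mock were high for PR and SA-marker protein genes, with a median log2 ratio of 2.77, at percentile 100 of 10000 random lists of like level. Heat shock proteins (2.65), plastid-encoded genes (2.63), markers of other cell types (1.63) and tryptophan, camalexin and indole glucosinolate genes (1.47) were at percentile 100 too, and the JA pathway (0.689) at 99.9. Photosynthesis genes (-0.487) were at percentile 0.06 and ABA response genes (-1.32) at 0.54. These ratios were computed after PR1 was seen, and the test on PR1 was chosen after its levels were seen. That plants of the Ribo-seq and the paired RNA-seq differed in SA state needs a percentile near the top in both genotypes, and the lower was 100; it cannot be told apart from other reasons, since the percentile is saturated and lists outside SA reached it too, a requirement added afterwards. In sair1-1 mock the ratio of the PR and SA-marker list was 3.75, that of heat shock proteins and of plastid-encoded genes 2.23, and that of the SA pathway 0.175 at percentile 94.2 (0.0994 at 89.6 in Col-0 mock). Under mock the PR and SA-marker list had the highest ratio in both genotypes. In Col-0 flg22 plastid-encoded genes stood higher, at 3.22 against 2.97. A fixed high translation of PR1 cannot be told apart from a changing one either: the fold between replicates in the paired RNA-seq was 88.9 times that in the Ribo-seq in Col-0 mock, but 3.26, 1.36 and 1.1 times in Col-0 flg22, sair1-1 mock and sair1-1 flg22. A bound of 10 was set for Col-0 mock, where 1 library makes the difference, and the demand that it hold in all 4 groups was added afterwards.

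SAIR1 itself moved with DC3000, by -0.51 ± 0.21 in Col-0 (adjusted p = 0.0482, up to 0.159 with a library left out), by 0.88 ± 0.20 in the libraries labelled sair1-1 (0.00519, or 0.0533 without its DC3000 replicate 2, fold 0.59 to 1.12) and by -1.18 ± 0.24 in those labelled SAIR1-YFP-OX2 (0.00152). The rRNA share was 5.54% in Col-0 DC3000 replicate 1, 3.87% in labelled sair1-1 DC3000 replicate 1 and 2.86% in labelled SAIR1-YFP-OX2 DC3000 replicate 2.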
